A study of Homo sapiens with 12 samples.

How the data were processed

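Chromatin accessibility was measured by ATAC-seq, in which Tn5 transposase inserts sequencing adapters into open DNA, in 12 libraries of the clear cell renal carcinoma line M1A-Cl6. Per the labels' protocols, doxycycline at 0.6 µg/ml induced Cas9 and the short hairpin RNA (shRNA), 50000 cells entered each reaction and Nextera reagents were used. The 4 groups of 3 libraries carried a control shRNA with a control guide RNA (shCtrl/sgCtrl), an shRNA against PAX8 with the control guide (shPAX8/sgCtrl), and the PAX8 shRNA with 1 of 2 guides against SMARCB1 (shPAX8/sgSMARCB1-1 and shPAX8/sgSMARCB1-2). The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

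The deposited data were 1 list of peak summits per library on the hg38 assembly. The score of each deposited summit was taken here as −log10 of a p- or q-value, as MACS2 writes it, since the sources used here do not state its unit. The tools named in the submitters' processing notes, without their roles, were cutadapt 2.10, FastQC 0.11.9, BWA 0.7.17 and MACS2 2.2.7.1. Caller settings, filters on duplicate or mitochondrial reads and any correction for the Tn5 insertion offset are not given in the sources used here. Read depth is unknown, and a longer list can reflect more reads as well as more open chromatin. The score was used only to order summits within their own list. A summit list holds no signal level, so a region that weakened but stayed above the caller's threshold counts as called.

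Summits on chromosomes 1 to 22 and X were kept, and each list was limited to its best-scoring 72897 summits, the length of the shortest list. Summits were merged into regions by taking the best-ranked unassigned summit and all unassigned summits within 250 bp of it. A region was called in a library where it held at least 1 of its summits. Genes, exons, introns and transcription start sites (TSS) came from GENCODE 44. A region within 1 kb of a TSS was termed a promoter region, and others were termed distal. Each region was assigned to the nearest protein-coding TSS within 50 kb, so a gene's region number counts open sites near its start and does not measure its expression.

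A region was counted as gained or lost in comparisons of 3 against 3 libraries when all libraries of 1 group and none of the other had it, which chance gives for 10% of regions called in exactly 3 of 6 libraries. No p-value per region was used there, because 3 against 3 cannot go below 0.1. The 6 sgSMARCB1 libraries were compared with the 3 shPAX8/sgCtrl libraries by Fisher's exact test per region, two-sided, with Benjamini-Hochberg adjustment over regions called in 3 to 6 of the 9 libraries. Region numbers per gene were tested with limma 3.58.1, with a trended variance, on log2 of regions per 100000 called regions plus 0.5. All 12 libraries entered 1 fit with 8 residual degrees of freedom, and genes needed a mean of at least 2 regions. The fold change on this scale understates the change of genes with few regions. Because region numbers are small whole numbers, replicates often tied and standard errors were then small.

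The 17 gene lists covered renal lineage transcription factors, proximal tubule function, hypoxia-inducible factor (HIF) targets, epithelial and mesenchymal markers, AP-1 factors, YAP and TEAD targets, SWI/SNF subunits, cell cycle genes, NF-κB and inflammatory genes, interferon-stimulated genes, HOX genes, housekeeping genes, and markers of neuronal, blood, endothelial and muscle cells. A list's value was the number of called regions assigned to its members per 10000 called regions. Motif shares were the percent of distal regions with a consensus string on either strand within 100 bp of the summit, for 23 strings of which 2 were controls made by reordering the letters of the AP-1 site. Lists, motif shares, list lengths and promoter shares were tested over libraries with exact two-sided permutation tests, whose p was 2 times the smaller tail and whose smallest p is 0.1 for 3 against 3 and 0.0238 for 6 against 3. Benjamini-Hochberg adjustment covered the lists or the motifs of a comparison. In simulated data for 6 against 3, 5 changed lists of 17 gave 0% recovered, because at least 9 must reach the smallest p, and 12 changed lists gave 99.7%. For motifs at least 11 of 23 must do so.

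Named genes were the 10 with the largest rise and the 10 with the largest fall per comparison, among genes past an adjusted p of 0.05 whose libraries did not overlap between the groups. Up to 10 list members per comparison that passed adjusted over the list alone were added, as were PAX8 and SMARCB1. The lists, motifs, tests, this rule and most alternatives were fixed before the data were examined. The alternatives were all deposited summits, the best-scoring 36448 summits, a score of at least 5, merging within 100 or 500 bp, TSS windows of 20 or 100 kb, a pseudocount of 2, no filter or a mean of at least 5 regions, only the libraries of the comparison, a replicate block, GC deciles, a motif window of 50 bp and each library left out. A further 4 alternatives were chosen after the data were seen, namely regions with no called region of the other group within 1 kb, distal regions only, list values per 10000 regions within 50 kb of a protein-coding TSS, and a permutation p from the size of the difference.

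Overlaps between comparisons that share control libraries were set beside 100 simulations of unchanged groups, from which the genes with the smallest p were taken in lists of the observed sizes. The procedures were tested on simulated data. With 200 genes changed by a factor of 0.5 or 2, limma recovered 30.5% and 18% for shPAX8, 2% and 36.5% for sgSMARCB1, and 13.5% and 28.5% for the difference between the guides, so many changes of that size would be missed. Unchanged genes were called as well, 11 and 10 beside 61 and 36 recovered for shPAX8, 6 and 15 beside 4 and 73 for sgSMARCB1, and 9 and 8 beside 27 and 57 for the guides. False calls thus exceeded the share that an adjusted p of 0.05 allows. The region counts recovered 100% of the simulated gained and lost regions. The setting fixed this, because changed regions were simulated in every library of their group and in none of the other. Beyond those, 22 and 13 unchanged regions were called for shPAX8 and sgSMARCB1, where all unchanged regions shared the same high call rate. The simulation held 20000 regions, of which 2000 changed in each direction. With each region's own call rate, simulated unchanged groups gave 749 lost and 746 gained regions for shPAX8. For sgSMARCB1 they gave 102 gained and 159 lost. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, pysam 0.24.0 and matplotlib 3.10.9, and R 4.3.3. Results for some items withheld for evaluation are not reported here.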

Results

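Open chromatin was mapped in 12 ATAC-seq libraries of M1A-Cl6, a clear cell renal carcinoma line, in 4 groups of 3. The series sets SMARCB1, a core subunit of the SWI/SNF chromatin remodelling complex, in the context of lineage fidelity in renal cancer. PAX8 is a lineage transcription factor of the kidney epithelium. The libraries carried a control or a PAX8 shRNA together with a control guide or 1 of 2 SMARCB1 guides. All 6 sgCtrl libraries came from 1 sequencing pool on lane 3 and all 6 sgSMARCB1 libraries from another on lane 4, so the pool and the SMARCB1 guides cannot be told apart. The sample titles also mark these sets with different letter codes whose meaning the labels do not give, and doxycycline lasted 1 week to 2 months with no duration stated per library.

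The libraries held between 72965 and 134288 deposited summits. Group means were 120269 ± 5517 summits for shCtrl/sgCtrl, 120814 ± 14403 for shPAX8/sgCtrl, 82206 ± 9673 for shPAX8/sgSMARCB1-1 and 78751 ± 7670 for shPAX8/sgSMARCB1-2 (SD, n = 3 each). In lists of equal length, the merged catalogue held 149915 regions, of which 28380 were called in all 12 libraries and 31472 in 1 library only. Replicates shared on average 77.3%, 71.1%, 66.9% and 70.2% of the regions called in either, in the same order of groups. The shPAX8/sgCtrl libraries shared 63.6% with shCtrl/sgCtrl, 41.0% with guide 1 and 54.8% with guide 2, and the guides shared 55.2% with each other.

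**Figure D1:**
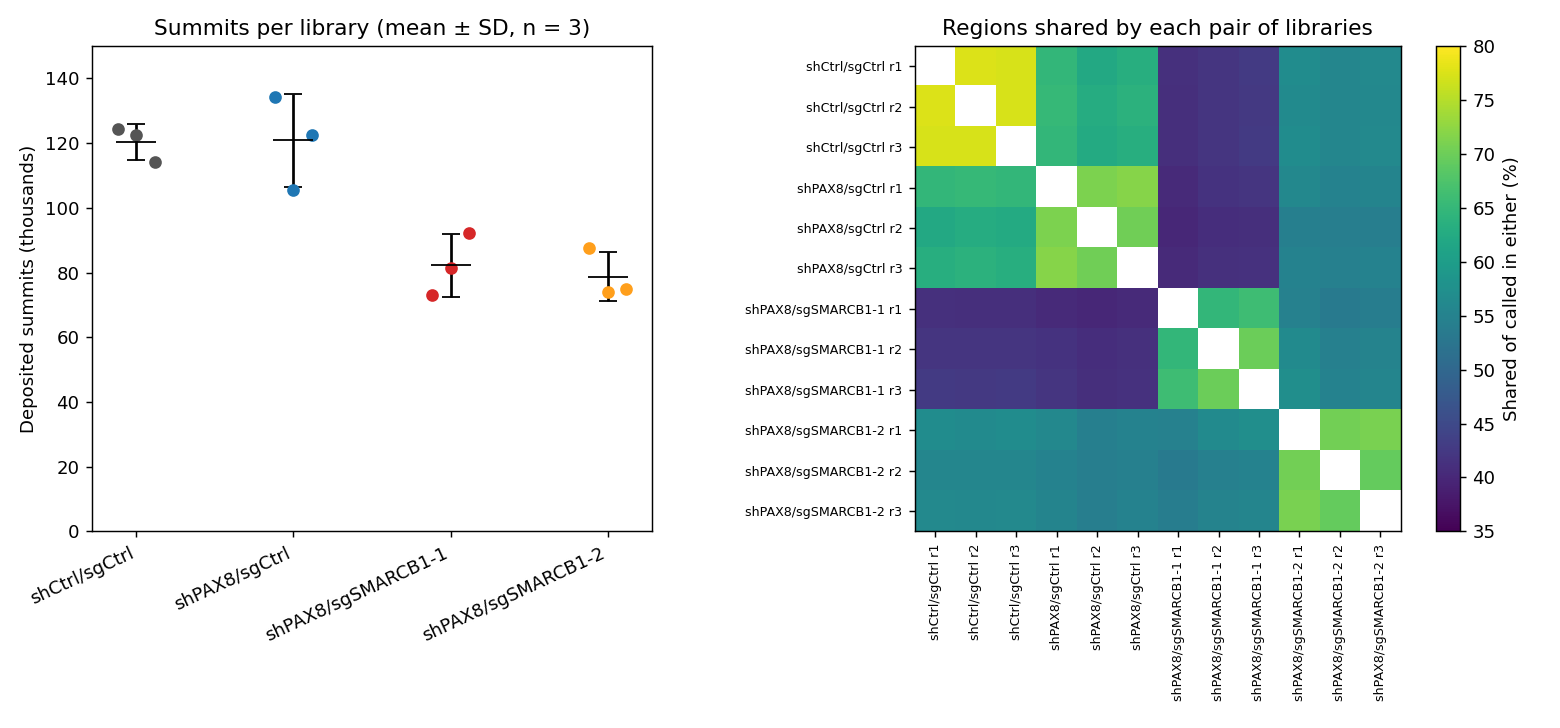
Left, deposited summits per library, with points for libraries and bars for the mean ± SD (n = 3), which were 120269 for shCtrl/sgCtrl and 78751 for shPAX8/sgSMARCB1-2. Right, percent of regions shared by each pair of libraries among regions called in either, where replicates averaged 66.9% to 77.3% and pairs of shPAX8/sgCtrl with guide 1 averaged 41.0%.

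The targeted genes kept open promoters in every library. A region within 1 kb of the PAX8 TSS (chromosome 2, position 113278921) was called in all 12 libraries, as was one near the SMARCB1 TSS (chromosome 22, position 23786966). PAX8 had 9 to 10 called regions within 50 kb in shCtrl/sgCtrl and 7 to 8 in shPAX8/sgCtrl, a log2 difference of −0.27 (SE 0.10) with a limma adjusted p of 0.171 over all genes and 0.0496 adjusted over the list alone. SMARCB1 had 1 to 2 regions in each library. Accessibility checks neither the knockdown of an mRNA nor the editing of a gene, so the labels were not checked by these values.

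The first comparison set the PAX8 shRNA against the control shRNA, both with the control guide. The HNF1 and PAX2/5/8 paired domain motifs were in fewer distal regions in shPAX8/sgCtrl, and the HNF4 motif stood at 0.943 times. The motif of HNF1, the hepatocyte nuclear factor family that drives tubule genes, was in 1.21% ± 0.0309 of distal regions against 1.51% ± 0.0115 in shCtrl/sgCtrl, 0.805 times as many (SD, n = 3 each). The PAX2/5/8 paired domain motif was in 0.861% ± 0.0192 against 1.03% ± 0.00874, and the NF-κB motif in 2.57% ± 0.0195 against 3.04% ± 0.0645. The TEAD motif stood higher at 10.3% against 9.65% and the motif of CTCF, the insulator and loop anchor protein, at 4.17% against 3.68%, 1.13 times as many, though its difference was −0.00241 percentage points with all deposited summits. AP-1 stood at 39.8% against 40.3%, 0.989 times as many. These libraries did not overlap between the groups, at p = 0.1 each in the exact two-sided permutation test, the smallest p that 10 splits can give, and none passed adjustment (adjusted p = 0.144). A reordered control string, at 1.54% against 1.61%, was separated in the same way, at 0.958 times.

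All 3 shPAX8/sgCtrl libraries and no shCtrl/sgCtrl library held 3489 regions, here termed gained, and 4333 regions were lost. Of 12632 regions called in exactly 3 of the 6 libraries, 61.9% were split by group, against 10% by chance. The sites differed between these sets, in a two-sided Fisher's exact test that compares regions and not libraries. The HNF1 motif was in 0.750% of gained and 2.64% of lost distal regions, the PAX motif in 0.438% and 1.76%, NF-κB in 1.31% and 4.42%, TEAD in 13.6% and 8.34%, and CTCF in 2.44% and 0.804%. Promoters made up 8.28% of the gained regions (95% Wilson interval 7.41 to 9.24) and 8.10% of the lost regions (7.32 to 8.95), compared with 23.6% of regions called in all 6 libraries. Some of these regions lay next to a region called in the other group, as when the summit of 1 wide open region moves. Leaving out those with such a neighbour within 1 kb gave 3021 gained and 3504 lost.

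The regions that best met the naming rule were such moved summits, for example at positions 96388825 and 96389192 of chromosome 7, near SLC25A13. Regions without a neighbour within 1 kb were therefore chosen after their values were seen. The gained ones lay in an intron of TXN, which encodes thioredoxin, 0.902 kb from its TSS (chromosome 9, 110255355 to 110255855), in an intron of MYL1 (chromosome 2, 210302335 to 210302835), and between genes on chromosome 8 (125986703 to 125987203). The lost ones lay between genes 18.9 kb from the TSS of MGST3 (chromosome 1, 165612051 to 165612551) and 90.3 kb from SP3 (chromosome 2, 173874820 to 173875320).

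The number of open regions near a gene rose for 164 genes and fell for 237 of 8113 tested with shPAX8. KLHL14 went from 8.33 to 1.33 regions, a log2 change of −2.41 (SE 0.26, limma adjusted p = 0.00152, n = 3 each). The homeobox gene DLX4 fell from 4.33 to 0.333 regions (−3.02, SE 0.46, adjusted p = 0.00883), and TYRO3, a receptor tyrosine kinase, fell from 2 regions in each library to a listed 0 (adjusted p = 0.000384). GLI1, the Hedgehog effector, ELF1, BNC2, JUNB, UGT1A6, DIXDC1 and C12orf75 also fell, by log2 changes between −2.23 and −1.78. The largest rises were FRMD1, listed at 0 in shCtrl/sgCtrl and at 3 regions in each shPAX8/sgCtrl library (adjusted p = 0.000384), and KCNMB1, from 0.667 to 4 (2.31, SE 0.43, adjusted p = 0.0201). MAGEF1, LDB3, ARFGEF1, FNDC1, YWHAB, TTC8, SNRNP48 and SLC25A30 rose by 1.30 to 1.44.

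These gene calls depended on the list length. With all deposited summits 5 genes rose and 11 fell, 0 of the 27 named genes past the threshold kept their call, and TYRO3, JUNB, SNRNP48, BIRC3 and NEB changed sign. Without shCtrl/sgCtrl replicates 1, 2 and 3 in turn 101, 154 and 108 genes fell, and without shPAX8/sgCtrl replicate 2 or shCtrl/sgCtrl replicates 1 or 3, 96, 105 and 106 rose.

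Few list members passed the adjusted test with shPAX8. Of 10 tested genes of proximal tubule function, 0 rose and 1 fell, the aminopeptidase ANPEP, from 9 to 4.67 regions (−0.90, SE 0.09, adjusted p = 0.00118), although it stood at 0.29 with the best-scoring 50% of the lists. Of 14 NF-κB and inflammatory genes 2 fell, BIRC3 from 6.67 to 3.33 (−0.93, SE 0.10, adjusted p = 0.0015), which stood at 0.18 with the best-scoring 50%, and the chemokine CXCL1 from 6 to 2.67 (−1.08, SE 0.17, adjusted p = 0.0105). Adjusted over the list alone, 3 fell. Of 14 renal lineage transcription factors, TFAP2A rose (0.42, adjusted p = 0.0499) and 0 fell, whereas adjusted over the list alone 2 rose and 4 fell. SIM1 was among those 4, at −0.30 and 0.0268 over the list. Of 15 epithelial markers, keratin 7 (KRT7) fell (−0.74, adjusted p = 0.0460) and 2 fell adjusted over the list alone. Of 19 mesenchymal markers the collagen gene COL1A2 rose from 3 to 7 regions (1.13, SE 0.12, adjusted p = 0.00139), and 2 rose adjusted over the list alone. The AP-1 factor JUNB fell (−2.06, SE 0.43, adjusted p = 0.0278), TEAD1 went from 6 to 5 regions (−0.25, adjusted p = 0.0128, but 0.13 with a 20 kb window), OAS2 of the interferon list rose from 1 to 2.67 (1.09, adjusted p = 0.0288) and the muscle gene NEB rose from 2 to 4.33 (0.98, adjusted p = 0.00569). TNNT2, cardiac troponin T, stood at 0.333 against 2 regions (−1.97, adjusted p = 0.0695 over all genes and 0.0125 over the muscle list alone). Among HIF targets, SWI/SNF subunits, cell cycle genes, housekeeping genes, HOX genes and blood and endothelial markers, 0 genes passed limma's adjusted test, of 1550 genes over all at an unadjusted p under 0.05.

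As sums over members, the proximal tubule list had 5.63 ± 0.273 regions per 10000 against 6.91 ± 0.419 in shCtrl/sgCtrl (0.815 times), the epithelial list 8.14 ± 0.556 against 10.1 ± 0.285 (0.806 times) and the NF-κB list 9.61 ± 0.363 against 11.5 ± 0.629 (0.834 times), with no overlap between the libraries (SD, n = 3 each). The AP-1 factor, neuronal and endothelial lists were also separated, at 0.909, 0.902 and 0.903 times. Each had p = 0.1 in the exact two-sided permutation test and an adjusted p of 0.283. The proximal tubule difference turned to 0.274 with the best-scoring 50% of the lists. The other 11 lists overlapped between the groups, with ratios from 0.923 for renal lineage factors to 1.07 for SWI/SNF subunits.

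The second comparison set both SMARCB1 guides, on the PAX8 shRNA background, against shPAX8/sgCtrl. AP-1 sites became rarer and CTCF sites more common among distal open regions. The AP-1 motif share fell from 39.8% ± 0.189 (n = 3) to 27.7% ± 5.53 (n = 6), with 22.7% ± 0.234 for guide 1 and 32.8% ± 0.0655 for guide 2. The share with the CTCF motif rose from 4.17% ± 0.0526 to 9.39% ± 1.83. TEAD fell from 10.3% to 8.35%, RUNX from 10.7% to 8.60%, MAF/NRF2 from 2.49% to 1.84% and the PAX motif from 0.861% to 0.683%, and GATA (0.850 times), MEF2 (0.863), C/EBP (0.928) and STAT (0.930) were lower. HNF1 rose from 1.21% to 1.46%, SP/KLF from 1.74% to 2.35%, IRF from 0.501% to 0.642%, and ETS also rose. These 14 motifs had the smallest p that 84 splits can give, 0.0238 in the exact two-sided permutation test, with an adjusted p of 0.0365, each shifted the same way in 6 of 6 libraries. One reordered control string passed as well, at 0.910 times, a larger shift than those of C/EBP, STAT and ETS (1.09 times), and C/EBP was in 2.01% of gained and 1.73% of lost distal regions, the other direction. With all deposited summits MAF/NRF2 and RUNX had adjusted p of 0.365 and 0.404.

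**Figure D2:**
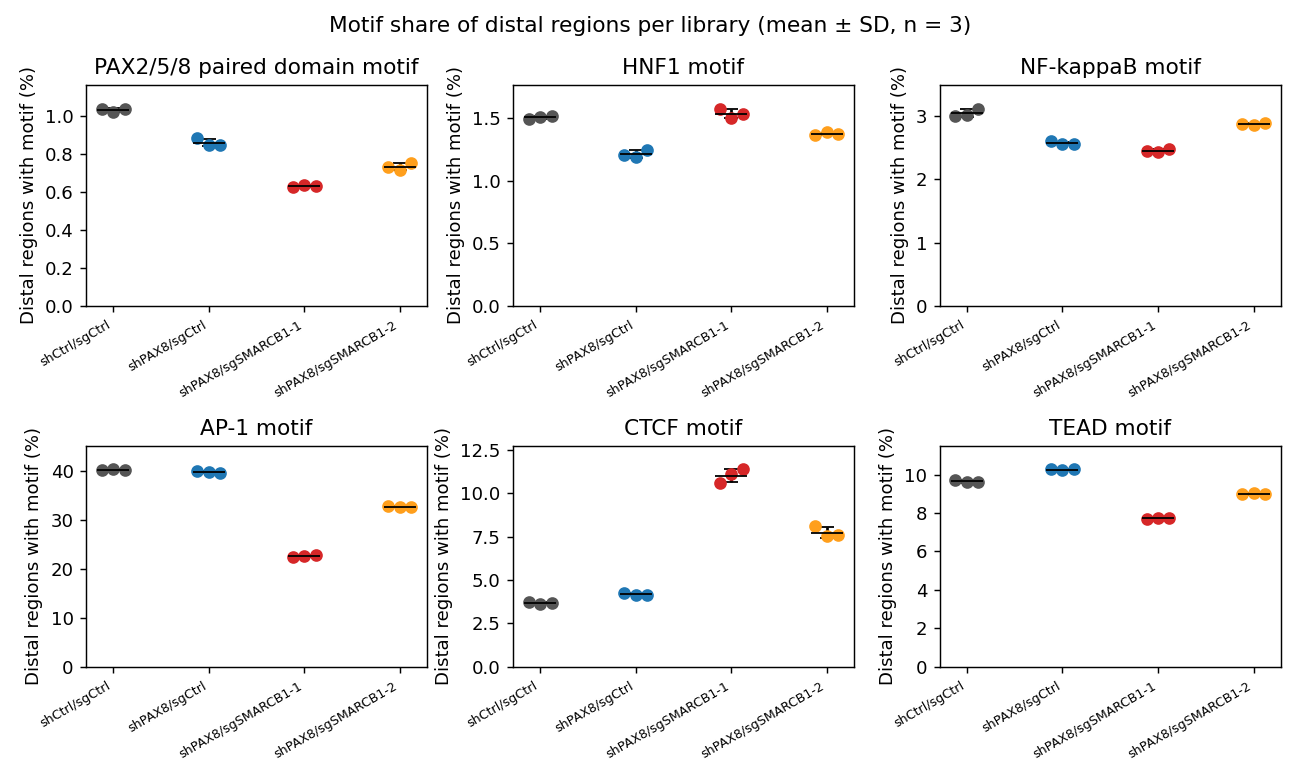
Percent of distal called regions with each of 6 motifs within 100 bp of the summit, with points for libraries and bars for the mean ± SD (n = 3). AP-1 stood at 39.8% in shPAX8/sgCtrl, 22.7% with guide 1 and 32.8% with guide 2, whereas CTCF stood at 4.17%, 11.0% and 7.74%.

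With sgSMARCB1, 3003 regions were called in all 6 libraries and in no shPAX8/sgCtrl library, and 7145 showed the reverse. Among lost distal regions 46.2% held the AP-1 motif and 0.218% the CTCF motif, compared with 8.69% and 22.5% of gained distal regions and 38.4% and 7.08% of distal regions called in all 9 libraries. In lists of equal length the AP-1 contrast thus lay mostly in its low share among gained regions. The lowest scores kept by the cut were 7.92 to 12.2 in shPAX8/sgCtrl libraries and 2.12 to 6.54 in sgSMARCB1 libraries. A gained region may therefore hold a deposited summit below the cut in shPAX8/sgCtrl, and 536 regions were gained with all deposited summits. The odds of AP-1 in gained over lost regions were 0.111, and 0.123 within deciles of GC content. Promoters made up 3.79% of lost regions (95% Wilson interval 3.37 to 4.26), 17.2% of gained regions (15.9 to 18.6) and 32.6% of regions called in all 9 libraries. Fisher's exact test per region called 0 of 47104 regions after adjustment, with a smallest adjusted p of 0.0553, and 15934 at an unadjusted p under 0.05, of which 6066 were higher and 9868 lower. Adjustment was missed because 21.5% of the regions had the smallest possible p of 0.0119, where 23.8% were needed. Against all 6 sgCtrl libraries, 5126 regions were higher and 7226 lower after adjustment.

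The balance of gained and lost regions depended on list length. Gained regions made up 29.6% in lists of equal length and 3.08% with all deposited summits, where 536 were gained and 16878 lost. The deposited lists themselves were shorter with sgSMARCB1, at 80479 ± 8033 summits (n = 6), 0.666 times those of shPAX8/sgCtrl (exact two-sided permutation p = 0.0238). In lists of equal length promoters took 25.1% ± 1.02 of called regions against 21.6% ± 0.667 (p = 0.0238 in the exact permutation test), a difference of 3.58 points that was 6.17 points with all deposited summits.

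Examples of lost regions, chosen after their values were seen among those without a neighbour within 1 kb, lay 243 kb from the TSS of FAT3 with AP-1 and MAF/NRF2 sites (chromosome 11, 91982033 to 91982533), in an intron of CNTNAP5 (chromosome 2, 124493918 to 124494418) and in an intron of CACNA1E with a RUNX site (chromosome 1, 181647247 to 181647747). All 3 were called in all 6 sgCtrl libraries. Gained regions lay in an intron of COBLL1 with AP-1 and HNF1 sites (chromosome 2, 164711211 to 164711711), next to the TSS of STK32A (chromosome 5, 147234701 to 147235201) and 405 kb from FAT4 with an AP-1 site (chromosome 4, 125719911 to 125720411). The COBLL1 region was also called in all 3 shCtrl/sgCtrl libraries, the STK32A region in 2 and the FAT4 region in 0.

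Near genes, region numbers rose for 1415 and fell for 858 of 8113 genes with sgSMARCB1, around a median change of 0.09. These changes are averages over the guides, and the libraries did not overlap between the groups for 1363 of the genes that rose and 407 of those that fell. TNNT2 rose from 0.333 to 5.17 regions (log2 3.26, SE 0.45, limma adjusted p = 0.00142, n = 6 against 3), and RASGEF1A from 0.667 to 5.33 (2.63, SE 0.37, adjusted p = 0.00151). DLX4, ELF1 and GLI1, which fell with shPAX8, rose to 3.5, 3.33 and 3.17 regions (2.75, 2.68 and 2.60), and TYRO3 rose from a listed 0 to 3 regions (adjusted p = 2.1e-05). ZNF396 rose from a listed 0 to 3.67, and LBHD2, TXNRD2 and MAP3K1 rose by 2.59 to 2.62. The atypical cadherin gene FAT2 fell from 9 to 1.5 regions (−2.37, SE 0.22, adjusted p = 0.000183), and TMEM244 from 6 to 1 (−2.59, SE 0.40, adjusted p = 0.00216). DRD2, a dopamine receptor, fell from 4 to 1.33 (adjusted p = 5.12e-06), being listed at 0 with guide 1 and at 2.67 with guide 2. TEKT3, GABRE, ABCB4, FGF16, SERPINB11, LYRM1 and HRNR fell by −2.38 to −1.96 on average. Of these 7 only TEKT3 passed with guide 2 alone (−1.08, adjusted p = 0.0278), while LYRM1 stood at −3.23 with guide 1 and −0.82 with guide 2 (adjusted p = 0.284) and FGF16 at −3.33 and −0.92 (0.189). TEKT3, GABRE, FGF16 and LYRM1 differed between the guides (adjusted p = 0.000471, 0.0135, 0.0108 and 0.0155), as did TMEM244 (0.0406). With all deposited summits the median of all genes stood at 0.19, 2063 genes rose, 790 fell and DLX4 stood at −0.02. Without shPAX8/sgCtrl replicate 3, 571 genes fell.

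**Figure D3:**
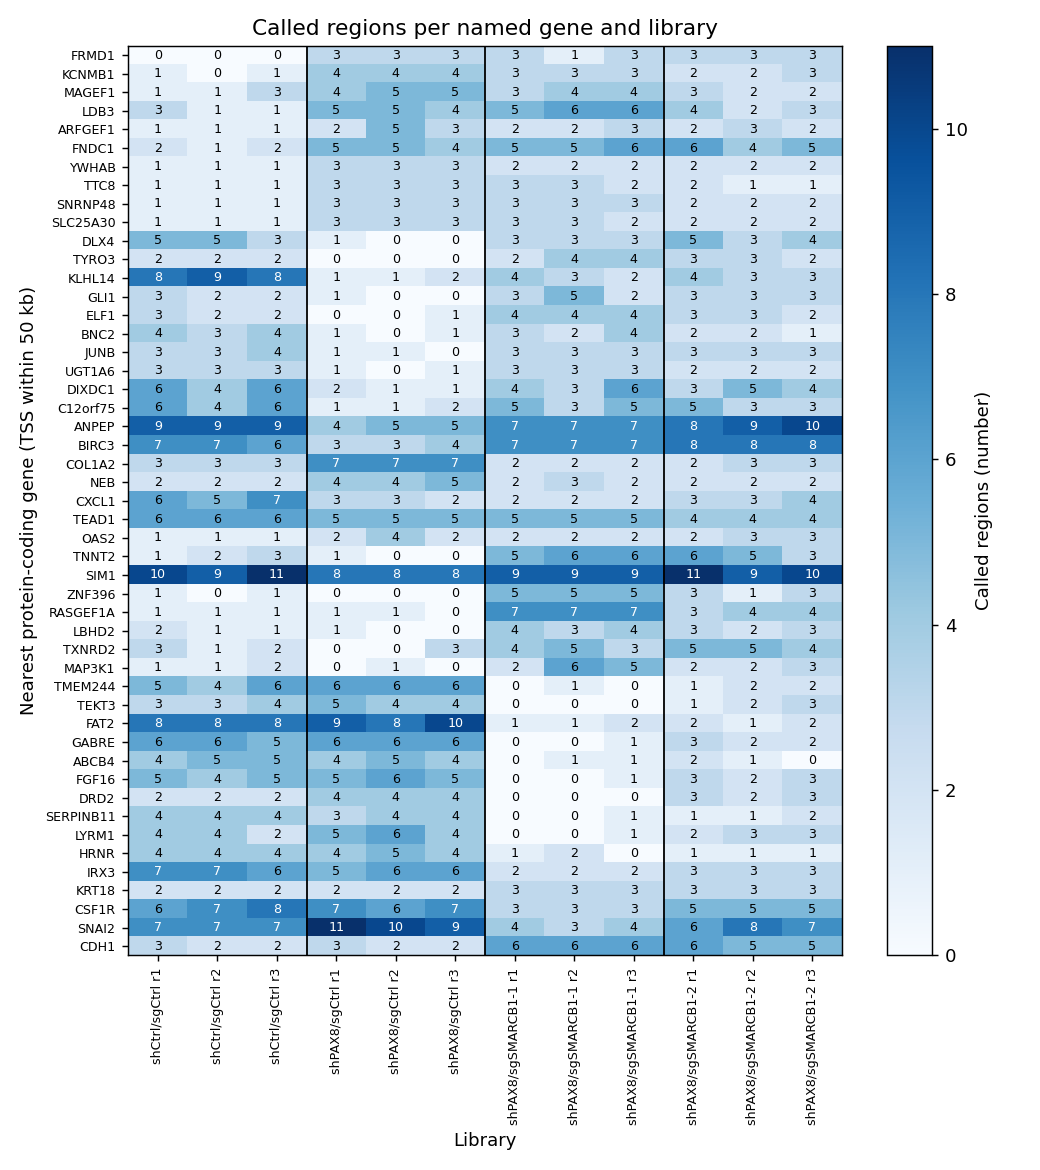
Number of called regions assigned to each named gene in each library, in lists of equal length, with darker cells for more regions and the 4 groups of 3 libraries divided by lines. KLHL14 averaged 8.33 regions in shCtrl/sgCtrl, 1.33 in shPAX8/sgCtrl and 3.17 over the sgSMARCB1 libraries, and FAT2 averaged 9 in shPAX8/sgCtrl and 1.5 over the sgSMARCB1 libraries.

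Single epithelial, mesenchymal and renal markers changed with sgSMARCB1. Of 15 tested epithelial markers 6 rose and 1 fell, with E-cadherin (CDH1) from 2.33 to 5.67 regions (1.18, SE 0.15, adjusted p = 0.000903), KRT18 from 2 to 3 (0.51, SE 0.04, adjusted p = 5.02e-05), KRT19 at 1.00 and MAL2 at −0.87. Adjusted over the list alone 6 rose and 2 fell. Of 19 mesenchymal markers 5 rose and 6 fell, and 6 and 6 adjusted over the list alone. COL1A2 fell from 7 to 2.33 (−1.47, SE 0.10, adjusted p = 4.56e-05), and SNAI2, which encodes the transcription factor Slug, from 10 to 5.33 (−0.93, SE 0.11, adjusted p = 0.000698), whereas ZEB1 rose by 1.44 and vimentin (VIM) by 0.47. Of 14 renal lineage factors 5 rose and 2 fell, also adjusted over the list alone, with POU3F3 at 1.05, SALL1 at −0.98 and IRX3 from 5.67 to 2.5 (−1.09, SE 0.07, adjusted p = 3.26e-05). Of 10 proximal tubule genes 3 rose and 0 fell, ANPEP from 4.67 to 8 (0.73, SE 0.08, adjusted p = 0.000498), the transporter SLC17A3 and ACMSD, and 4 rose adjusted over the list alone.

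Of 13 HIF targets 4 rose and 0 fell, namely VEGFA (1.33), ADM (0.62), CCND1 (1.69) and HK2 (0.33), and 5 rose adjusted over the list alone. Of 8 interferon-stimulated genes 5 rose and 0 fell, including IFIH1 (1.19) and IFIT1 (0.57), with 5 also over the list alone. Of 14 NF-κB genes 2 rose, BIRC3 from 3.33 to 7.5 (1.10, SE 0.09, adjusted p = 6.17e-05) and ICAM1 (0.87), and of 11 AP-1 factors 3 rose and 1 fell, with JUNB at 1.94 and BATF3 at −0.47. Of 17 SWI/SNF subunits 4 rose and 1 fell, with BCL7A at 1.54 and SMARCA2, a catalytic ATPase, at −0.71. Of 14 YAP and TEAD targets 3 rose and 1 fell, of 11 HOX genes 3 rose, and of 10 cell cycle and 12 housekeeping genes 1 each rose, CCNE2 (0.75) and ACTB (0.58). Of 9 endothelial markers 3 fell, KDR (−1.13), SOX17 and TEK, and ESAM rose. Of 5 blood markers CSF1R (−0.72, SE 0.08, adjusted p = 0.000604) and LCP2 fell, and of 7 neuronal markers GAP43 fell, though not adjusted over the list alone. Of 6 muscle markers TNNT2 and TTN rose and NEB fell (−0.90). Some of these averages hide a difference between the guides by limma, such as TEK at −0.84 with guide 1 and 0.00 with guide 2 (adjusted p = 0.00316), POU3F3 at 1.66 and 0.44 (0.0403), SMARCA2 at −1.09 and −0.34 (0.0164) and ACTB at 0.89 and 0.28 (0.0229).

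As sums per 10000 called regions, 14 of 17 lists were higher with sgSMARCB1, each at an exact two-sided permutation p of 0.0238 and an adjusted p of 0.0289, in 6 of 6 libraries. HOX genes stood at 8.32 ± 0.683 against 5.58 ± 0.396 (1.49 times), interferon-stimulated genes at 1.29 times, epithelial markers at 10.2 ± 0.419 against 8.14 ± 0.556 (1.25 times) and proximal tubule genes at 7.04 ± 0.437 against 5.63 ± 0.273 (1.25 times). Renal lineage factors and HIF targets stood at 1.22 times, SWI/SNF subunits at 1.20, muscle markers at 1.19, AP-1 factors at 1.18, cell cycle genes at 1.16, NF-κB genes at 1.10, YAP and TEAD targets at 1.09 and neuronal markers at 1.07. Housekeeping genes were 1.21 times higher as well. Mesenchymal markers stood at 0.965 times (adjusted p = 0.524), endothelial markers at 0.904 times (0.329) and blood markers at 0.830 times (0.0540). Per 10000 regions within 50 kb of a protein-coding TSS, 0 lists passed the adjusted permutation test and 8 had an unadjusted exact permutation p under 0.05, of which 5 were higher and 3 lower, and YAP and TEAD targets, NF-κB genes and neuronal markers stood lower than in shPAX8/sgCtrl. The proximal tubule difference turned to −0.229 with the best-scoring 50% of the lists.

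Both comparisons can be set side by side, because regions lost with shPAX8 may be open again with sgSMARCB1. They share the 3 shPAX8/sgCtrl libraries, which give opposite changes by chance and are too few to be divided. In lists of equal length ANPEP, BIRC3, KLHL14, DLX4, JUNB and TYRO3 fell with shPAX8 and rose with sgSMARCB1, while COL1A2 and NEB did the reverse. With all deposited summits TYRO3, JUNB, BIRC3 and NEB changed sign with shPAX8, and DLX4 did so with sgSMARCB1. With the best-scoring 36448 summits ANPEP and BIRC3 changed sign with shPAX8. Of 27 named genes past the threshold with shPAX8, 0 kept their call with all deposited summits. Of 237 genes that fell with shPAX8, 155 rose with sgSMARCB1, compared with 41.3 for independent lists. Lists of the same sizes from 100 simulations of unchanged groups with the same controls shared 167 on average (145 to 184). Of 164 that rose, 67 fell with sgSMARCB1, compared with 17.3 for independent lists and 103 in the simulations (87 to 114). In lists of these sizes the gene overlaps were therefore no larger than the shared libraries can give. Among genes past limma's adjusted test, the simulations shared on average 0.01 for the 155 and 0 for the 67. They called only 0.04 genes on average in each comparison, against 401 with shPAX8 and 2273 with sgSMARCB1. The correlation of the log2 changes, −0.414, was also weaker than in the simulations, at −0.577 (−0.603 to −0.542). The covariance, to which shared libraries add the same amount with or without real effects, was −0.0813, against −0.0276 in the simulations (−0.0295 to −0.0254). The simulations used a spread averaged over the groups, and the spread within shPAX8/sgCtrl alone gives −0.0316.

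For single regions the covariance of the call shares was −0.0583, 2.13 times the −0.0274 that the spread within shPAX8/sgCtrl gives by itself, and 1.74 to 1.77 times when 1 shPAX8/sgCtrl library was left out. Of 4333 lost regions 454 (10.5%) were called in all 6 sgSMARCB1 libraries, where independent lists give 86.8. Of 3489 gained regions 2025 (58.0%) were called in no sgSMARCB1 library, where independent lists give 166. A region called in all or in none of the shPAX8/sgCtrl libraries can change in only 1 direction in each comparison, which favours opposite changes. Independent lists ignore this and also give 207 regions lost in both comparisons, where 0 were seen and none is possible. The values 86.8 and 166 are therefore too low. Part of the excesses over them may also come from the spread of the shared libraries. Simulations of unchanged groups gave 28.5 and 56 such regions, from much shorter lists of 749 lost and 102 gained and of 746 gained and 159 lost regions, so these counts cannot be compared directly. Without shPAX8/sgCtrl replicates 1 and 3, 802 and 713 regions were lost and called again. With all deposited summits fewer regions were lost and called again, and more were gained and then absent.

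Most regions lost with shPAX8 were not called in a given sgSMARCB1 library. On average 23.5% ± 1.01 of the 4333 regions were called in guide 1 libraries and 28.6% ± 1.27 in guide 2 libraries (SD, n = 3 each), compared with 48.5% of all regions. Regions gained with shPAX8 were absent from all 3 libraries of guide 1 in 75.3% and of guide 2 in 61.8%, and regions lost with shPAX8 in 68.7% and 60.7%, so absence was hardly particular to the gained ones.

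The third comparison set guide 2 against guide 1, within 1 pool and lane. AP-1 sites were in 32.8% ± 0.0655 of distal regions with guide 2 and in 22.7% ± 0.234 with guide 1, and CTCF sites in 7.74% ± 0.314 and 11.0% ± 0.394 (SD, n = 3 each). Guide 1 stood further from shPAX8/sgCtrl, with 11323 gained and 15600 lost regions against 4927 and 7898 for guide 2, and with all deposited summits 4527 and 29002 against 1104 and 19335. Between the guides, 6499 regions were called in all guide 2 and no guide 1 libraries and 4005 the reverse, and 66.6% of 15760 regions called in exactly 3 of the 6 libraries were split by guide, against 10% by chance. Regions called with guide 2 and not with guide 1 held the AP-1 motif in 45.9% of distal regions and the reverse set in 5.65%, in a Fisher's exact test that compares regions. Without guide 1 replicate 1 the reverse set held 6714 regions. Of 1314 genes that rose with guide 1, 610 also rose with guide 2, where independent lists give 138 and simulations of unchanged groups sharing the controls, with lists of the same sizes, 403 (369 to 438). The same sign was seen for 1275, against 1041 simulated (1003 to 1101). Of 1011 that fell, 286 also fell with guide 2, against 53.5 for independent lists and 207 simulated (186 to 234), and 826 had the same sign, within the simulated 787 to 843. The covariance of the log2 changes of the guides was 0.219, against 0.0275 simulated (0.0253 to 0.0296). Part of the excess over independent lists may come from the shared controls. Both guides also shared a pool and lane apart from those controls. That may give changes common to the guides and cannot be told apart from SMARCB1 loss.

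With guide 2 compared with guide 1, 540 genes had more open regions and 247 fewer by limma, and the counts were 201 and 164 in a fit of these 6 libraries alone. Some mesenchymal and endothelial markers had more regions with guide 2. SNAI2 had 7 regions against 3.67 (0.87, SE 0.13, adjusted p = 0.00396), and COL5A1 and THY1 were higher by 0.90 and 2.06. Of 19 mesenchymal markers 3 were higher and 0 lower, and 8 and 1 adjusted over the list alone. The endothelial markers PECAM1, CLDN5 and TEK were higher by 2.68, 2.85 and 0.84 and CDH5 lower by −0.78, of 9 tested. SMARCA2 was higher by 0.74. The mesenchymal list stood at 16.1 ± 0.715 per 10000 against 13.1 ± 0.253 (1.23 times) and the endothelial list at 1.24 times, while HOX genes stood at 0.880 times, each at p = 0.1 in the exact two-sided permutation test, the smallest that 10 splits can give, and not past adjustment (adjusted p = 0.189).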

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

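The weighing of list length and the tests of other splits were chosen after the result was seen, whereas limma's tests were planned. The comparison of ranks was written down before its result, with its SD over guide 2 libraries. Groups of 3 libraries were not tested for a library far from the others.

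Both guides target SMARCB1, yet the number of open regions differed between them for 787 genes in limma's test of the difference. At 10 genes the guides passed the adjusted test in opposite directions from shPAX8/sgCtrl. BCL2 stood at 0.89 with guide 1 and −0.79 with guide 2, a log2 difference of −1.68 (limma adjusted p = 6.06e-05), and GBP5 at −1.13 and 1.01, a difference of 2.14 (adjusted p = 6.72e-05). The differences of guide 2 from guide 1 were −1.53 for CDC7, 1.26 for DNAI2, −1.78 for FBXO4, −1.55 for MCCC1, −0.67 for SPATA6, 0.62 for TNIP1, 0.92 for USPL1 and 1.55 for ZNF41. BCL2, CDC7 and MCCC1 had the same value of −0.79 with guide 2, as steps between small whole region numbers give. Standard errors are small where replicates tie, so these opposite directions may rest on steps of few regions. Every guide 1 library and every guide 2 library also lay on opposite sides of the mean of shPAX8/sgCtrl for the mesenchymal list, which was 2.97 regions per 10000 higher with guide 2. Guide 2 libraries overlapped single shPAX8/sgCtrl libraries for this list, with a lowest of 15.3 against a highest of 15.4. Opposite sides were also seen for the HNF4, NF-κB and FOX motifs, without such overlap, and their shares were higher with guide 2 by 0.201, 0.419 and 0.70 percentage points. For this list and these motifs the opposite directions were not tested.

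The distance of guide 1 from shPAX8/sgCtrl was weighed as the first pattern. In lists of equal length guide 1 gave 2.1 times the gained and lost regions of guide 2. The pattern was counted in those same lists, so this ratio does not test list length. The deposited lists of the guides overlapped in length, with means of 82206 and 78751 summits (exact two-sided permutation p = 0.7). A candidate explanation is that guide 2 libraries hold a smaller form of the guide 1 change. The regions tested were lost with guide 1 but called in all guide 2 and all shCtrl/sgCtrl libraries (3638 regions). Their ranks were worse in guide 2 than in shCtrl/sgCtrl, by a median of 19404 ± 281 places (SD, n = 3). This was measured beyond regions of like rank that guide 1 kept, which were called in all 12 libraries. That explanation needs such a shift. The shift also holds what shPAX8 and the pool did to these regions, so it does not single the explanation out. The pool stays open for the part the guides share, and editing efficiency and doxycycline duration were not measured.

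Other splits of the same libraries gave smaller counts. Of the 10 splits of the guide libraries, 1 gave as many separated regions as the real one, itself, with 10504 against a highest other of 818, and the genes stood at 787 against 14. For shPAX8 against shCtrl/sgCtrl 1 of 10 splits, the real one, gave as many, with 7822 regions against 609 and 401 genes against 12. In both designs 10 splits are too few for a share under 0.05. For sgSMARCB1 against shPAX8/sgCtrl 1 of 84 splits, the real one, gave as many, with 10148 regions against 7522 and 1659 genes in a fit of the 9 libraries against 974, so a chance division of these libraries can be excluded. Whether replicates were separate cultures is not stated, and with only 3 ways to set 1 group apart, chance between cultures was not tested. The highest other split set guide 1 against guide 2 and shPAX8/sgCtrl together, a structure of the samples, and the next gave 1023 regions and 70 genes.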

How the results depend on the processing

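The restriction to regions with no neighbour within 1 kb, distal regions, list values per regions within 50 kb of a TSS and the p from the size of the difference were chosen after the results were seen, and all other tests here were planned. The causes of the changes below were not tested except where construction gives them. Depth is unknown and limits what can be said of regions near the calling threshold. The 15 motifs past the adjusted test, the reordered control included, kept direction and side of the threshold with the best-scoring 50%, merging at 100 or 500 bp, a 50 bp motif window and the p from the size of the difference, and 13 did so with all deposited summits. Of 29 named genes past the threshold with sgSMARCB1, 22 kept their call with all deposited summits, 27 with a 100 kb window and 29 with a pseudocount of 2. Of 27 with shPAX8, 0 kept it with all deposited summits, 10 in a fit of the comparison's libraries alone and 27 with a pseudocount of 2.

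Region counts followed the list length. With the best-scoring 50%, shPAX8 gained 2061 and lost 2322 regions, sgSMARCB1 gained 1957 and lost 4426, and 1303 regions gained with shPAX8 were lost with sgSMARCB1. Called in the best-scoring 50% and absent from the equal-length lists of the other group were 288 gained and 353 lost with shPAX8, 112 and 1163 with sgSMARCB1, and 856 and 180 for guide 2 against guide 1. All deposited summits gave 536 gained and 16878 lost with sgSMARCB1, 129 lost with shPAX8 and gained with sgSMARCB1, and 3073 the reverse, and a score of at least 5 gave 534 and 15920. For regions lost, sgSMARCB1-2 minus sgSMARCB1-1, leaving out 1 library gave 5140 to 6714 (6714 without guide 1 replicate 1), and it gave 482 to 802 regions lost with shPAX8 and gained with sgSMARCB1 (802 and 713 without shPAX8/sgCtrl replicates 1 and 3).

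Fisher's exact test for sgSMARCB1, which passed 0 regions after adjustment in either direction and 15934 at an unadjusted p under 0.05, passed 536 higher and 16878 lower with all deposited summits, 1957 and 4426 with the best-scoring 50%, 534 and 15920 with a score of at least 5, 2989 and 7009 with merging at 500 bp, and 5126 and 7226 against all 6 sgCtrl libraries. Leaving out 1 library gave 0 to 3967 higher and 0 to 7935 lower. Both counts were 0 whichever shPAX8/sgCtrl library was left out, and at least 3157 and 7291 whichever sgSMARCB1 library was.

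With the best-scoring 50%, the promoter share differed by −1.09 percentage points with shPAX8 and −2.05 for guide 2 against guide 1 (exact permutation p = 0.1 each). For promoter percent, sgSMARCB1 (both guides) minus sgCtrl, the difference was 6.17 points with all deposited summits and 7.07 with the best-scoring 50%. When 1 library was left out, the sgSMARCB1 differences in summits ranged from −47925 to −33598, lowest without shPAX8/sgCtrl replicate 2 and highest without replicate 1, and in promoter share from 3.19 to 3.79, with exact permutation p = 0.0714, the smallest possible, without a shPAX8/sgCtrl library.

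For gene lists with sgSMARCB1, the 14 higher became 9 with merging at 500 bp, 9 with a 100 kb window and 0 per regions within 50 kb of a TSS (8 lists, higher or lower, at an unadjusted exact permutation p under 0.05), and leaving out 1 library gave 0, by construction without any shPAX8/sgCtrl library, to 14. Lower lists numbered 1 with the best-scoring 50%, 2 with merging at 500 bp and 1 with the p from the size of the difference, and 0 to 1 when 1 library was left out (1 without guide 2 replicate 1). The proximal tubule list reversed to −0.229 with the best-scoring 50%. Per regions within 50 kb of a TSS, YAP and TEAD targets reversed to −0.425, NF-κB genes to −0.0386 and neuronal markers to −0.295 while HOX genes, epithelial markers and mesenchymal markers stood at 1.35, 1.13 and 0.873 times. Neuronal markers reversed to −0.640 with a 100 kb window. For motifs, leaving out any library gave 0 higher and 0 lower after adjustment. Without a shPAX8/sgCtrl library too few splits remain for an exact permutation p under 0.05. Without an sgSMARCB1 library 5 motifs were higher and 10 lower at an unadjusted exact permutation p under 0.05, too few of 23 for the adjustment.

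Genes that rose with shPAX8 numbered 5 with all deposited summits, 63 and 257 with 20 and 100 kb windows, 104 with distal regions only, 355 without a filter and 20 with a mean of at least 5, and 96 to 155 when 1 library was left out (96 without shPAX8/sgCtrl replicate 2, and 105 and 106 without shCtrl/sgCtrl replicates 1 and 3). Genes that fell numbered 11 with all deposited summits, 147 with the best-scoring 50%, 101 with 20 kb, 430 without a filter and 81 with a mean of at least 5, and 101 to 223 when 1 library was left out (101, 154 and 108 without shCtrl/sgCtrl replicates 1, 2 and 3). With sgSMARCB1, 632 rose and 566 fell with the best-scoring 50%, 809 and 394 with 20 kb, 2729 and 1382 without a filter and 325 and 254 with a mean of at least 5, 915 rose with distal regions only, and 571 to 854 fell when 1 library was left out (571 without shPAX8/sgCtrl replicate 3). For guide 2 against guide 1, 280 rose and 102 fell with 20 kb, 224 and 58 with a mean of at least 5, and 201 and 164 in a fit of these libraries alone, and 383 fell with 100 kb and 581 without a filter. The mean and window settings also change how many genes are tested.

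Some named genes changed sign with shPAX8. With all deposited summits SNRNP48 stood at −0.33, TYRO3 at 0.17, JUNB at 0.00325, BIRC3 at 0.00496 and NEB at −0.0763, with the best-scoring 50% ANPEP at 0.29 and BIRC3 at 0.18, and with a 20 kb window TEAD1 at 0.13. With sgSMARCB1, DLX4 stood at −0.0189 with all deposited summits.

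Replicate numbers did not pair the libraries, with correlations of same-numbered deviations from −0.0375 to 0.0346. With a replicate block, the sgSMARCB1 differences of −40335 summits and 3.58 points of promoter share had exact permutation p = 0.0741, the smallest possible, and 0 lists and 0 motifs, higher or lower, passed for that reason. The block gave 117 genes that rose and 165 that fell with shPAX8, and 1280 and 788 with sgSMARCB1.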

Other observations

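The tests of library pool, weak summits, GC content, shared libraries and preparation were chosen after the result was seen, although the best-scoring 50% of the lists and the GC deciles they use were planned. Limma's and Fisher's exact tests were planned, and the test of moved summits was written down before its result.

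Regions open with guide 2 and not with guide 1 carried sites of several other factors. The RUNX motif was in 17.9% of these distal regions against 4.35% of the reverse set, the FOX motif in 5.82% against 1.92%, and the HNF4 motif in 1.29% against 0.339%, in Fisher's exact tests that compare regions. CTCF was in 0.348% against 13.6%. Of 7 neuronal markers SNAP25 (0.67) and NCAM1 (0.97) had more regions with guide 2 by limma (adjusted p = 0.00711 and 0.00791), and of 14 NF-κB and inflammatory genes CXCL1 had more (0.63) and the chemokine CCL2 fewer (−1.04). Of 17 SWI/SNF subunits, SMARCD1 had more (0.51) and BRD7 fewer (−0.60).

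The second pattern was the lower AP-1 and higher CTCF share with sgSMARCB1. Shorter lists with weak summits at their end do not account for its AP-1 part. In the best-scoring 50% of the lists the AP-1 difference was −12.6 percentage points, against −12.1 over whole lists. The shares there were 26.9% with guide 1, 40.4% with guide 2 and 46.2% in shPAX8/sgCtrl. GC content does not remove the AP-1 contrast of gained and lost distal regions, with odds of 0.123 within GC deciles. The CTCF part was not weighed in this way, though its higher share stayed past the adjusted test with the best-scoring 50%. The library pool cannot account for the AP-1 difference of 10.1 points between guides of 1 pool. For the part both guides share, of which guide 2 shows −7.09 points, the pool cannot be told apart from SMARCB1 loss, because no sgCtrl library was in the sgSMARCB1 pool.

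The third pattern was that some genes and regions changed by shPAX8 went the other way with sgSMARCB1. Of 4333 regions lost with shPAX8, 454 (10.5%) were called in every sgSMARCB1 library. Of 3489 gained regions, 2025 (58.0%) were called in none, though absence was hardly particular to the gained ones. Both counts depended on list length, the first being lower and the second higher with all deposited summits. In simulated lists of the observed sizes, the shared shPAX8/sgCtrl libraries give as many shared genes by chance, 145 to 184 for the 155 seen. They also give a stronger correlation, −0.577 against −0.414. Among genes past limma's adjusted test the simulations shared 0.01 on average, having called 0.04 with shPAX8 against 401. The spread within the shared libraries does not by itself give the covariance, which was −0.0813 for genes against a simulated −0.0295 to −0.0254. The spread of shPAX8/sgCtrl alone gives −0.0316, and the ratio to it was 1.96 to 2.13 when 1 of these libraries was left out. A shift common to these libraries would add to the covariance and is not counted in their spread. For the call shares of regions the covariance was 2.13 times the part of that spread, though shares have bounds that favour opposite changes. Moved summits do not account for most overlapping regions, since 89.0% of them had no called region of the other group within 1 kb. A preparation difference of the shPAX8/sgCtrl libraries as a group may give the same 454 regions and cannot be told apart from shPAX8, because these were the only libraries with shPAX8 and the control guide.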
